A study of Mus musculus with 12 samples.

How the data were processed

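Single-cell RNA was profiled in dissociated back skin of neonatal mice at postnatal day 0 (PD0), day 2 (PD2) and day 4 (PD4), and at PD4 after treatment with TSA (group TPD4). Each of the 4 groups held 3 libraries. TSA is the abbreviation commonly used for trichostatin A, an inhibitor of histone deacetylases, and the labels give only the abbreviation, a dose of 5 µg per g of body weight into the peritoneum, and a duration of 4 days. The PD4 libraries are given as untreated, so no group received the vehicle alone. Per the labels, dermal and epidermal suspensions were mixed in equal parts, dead cells were removed, and droplet libraries of transcript 3' ends were sequenced. The labels do not state whether the replicates came from separate animals or litters.

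The deposited tables hold raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 4.0.0 against mm10, 1 table per library, limited to the barcodes that program called as cells. All 12 tables list the same 32285 genes. No normalisation or pooling by the authors was found in the values. Gene coordinates are those of GENCODE release M21 on mm10, counted from 1. The tables held 174216 barcodes.

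Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 148281. Doublets were called in each library with Scrublet as implemented in scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes. The automatic threshold failed in PD2 replicate 3, which was given the median threshold of the other libraries. Removing 7841 called doublets and 1543 cells of clusters in which at least 50% of cells were called doublets left 138897 cells. Counts were scaled per cell, log transformed, and reduced to 2000 variable genes and 30 principal components, and cells were clustered with Leiden (igraph 0.11.9) on 15 nearest neighbours at resolution 1, without integration of libraries. Of 49 clusters, 32 were named into 16 classes holding 113737 cells. A name required at least 20 cells, and at least 50% and at least 3 of the class's markers at 100 CPM or more and at 10% or more of the highest cluster. It was withheld where the 10 leading genes held more markers of another class, or where depth was under 1/3 of the library median and no marker led. Names end in "-like" because they rest on RNA alone. Fibroblast-like cells were clustered again at resolution 0.8 without cell cycle genes.

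UMI counts were summed per library over the cells of each class, and 4 classes were tested, namely fibroblast-like, keratinocyte-like, endothelial-like and macrophage-like cells. The sums of fibroblast-like cells held 8924940 to 65378317 UMIs per library and those of keratinocyte-like cells 21169965 to 81096502. The endothelial-like sums held 97951 to 1637045 UMIs from 11 to 199 cells and the macrophage-like sums 274626 to 1186971 UMIs from 26 to 147 cells. Genes passing filterByExpr were fitted with edgeR 4.0.16 (quasi-likelihood, TMM, all 12 libraries, no covariates), and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene in the text is two-sided and from edgeR unless another tool is named. Levels are CPM, UMI counts scaled to the class sum on TMM-adjusted library sizes, as mean ± SD with n = 3 libraries. Fold changes are log2 values of the fit with their standard errors (SE), and zero counts set a floor of 3 counts over the group. Floors cover counting error only.

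Sets of genes were tested with camera (limma 3.58.1) at its preset correlation of 0.01, which makes calls easily. Each list result therefore carries the adjusted p with a correlation estimated from the data. Across the 85 list results described, 67 preset calls were lost with an estimated correlation. The rotation test fry, which asks whether a list's genes move on balance 1 way, was also run. A difference in the TSA change between fibroblast-like and keratinocyte-like cells was tested as an edgeR interaction with library as a block. Shares of cells were compared by two-sided exact permutation tests, whose smallest p with 3 against 3 libraries is 0.1, adjusted over 68 tests. A cell counted as cycling with UMIs of at least 2 of 8 G2/M genes after thinning to 2000 UMIs.

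The comparisons, tests, 40 gene lists, class markers, alternatives and the rule for named genes were fixed before the data were examined. The rule took genes past the threshold whose libraries did not overlap between groups, with a mean of at least 20 CPM in the higher group and at least 1/5 of the level of each other tested class, without gene models, mitochondrial, ribosomal, haemoglobin and sex-linked marker genes. From these it took the 8 largest rises and falls in fibroblast-like cells for PD4 vs PD0 and TPD4 vs PD4, and 5 and 5 elsewhere. It added up to 4 members with the smallest adjusted p of each list described and 13 genes always given in fibroblast-like cells. The results of 3 genes are not reported here. Chosen after the data were seen were the Scrublet threshold of PD2 replicate 3, the 100 CPM minimum for markers, the rule on leading markers, resolution 0.8, 4 further gene lists and alternatives named as such.

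Alternatives were DESeq2 1.42.0, RLE factors, a mean of at least 20 CPM, no filter on low counts, fits of only the 6 libraries compared, a minimum fold of 1.5 (glmTreat), stricter cells (at least 1000 genes, at most 5% mitochondrial UMIs), no doublet removal, resolution 2, sums without cycling cells, sums thinned to the lowest library, removal of genes under 1/10 of another class, and each library left out. The labels name no pairs, but replicate numbers were tested as blocks. Residuals of same-numbered libraries correlated by over 0.1 in every pair for fibroblast-like PD2 vs PD0, PD4 vs PD0 and TPD4 vs PD4, where a blocked count that differs by over 1.5 times stands beside its result. That reading was made after correlations and blocked counts had both been seen.

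The fits were tested on simulated data with 200 changed genes among 12 simulated libraries shaped like these. For fibroblast-like TPD4 vs PD4, edgeR recovered 3 of 67 genes changed 1.5-fold, 32 of 67 changed 2-fold and 55 of 66 changed 4-fold, with 5 false calls. The numbers were 13, 37 and 60 in keratinocyte-like, 2, 9 and 51 in endothelial-like, 1, 18 and 52 in macrophage-like cells, and 0, 9 and 51 for the interaction. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.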

Results

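The series concerns chromatin remodelling and the maturation of fibroblasts in the dermis after birth. It holds 12 single-cell RNA libraries of mouse back skin, 3 per group. Total depth was 111838747 to 161553864 UMIs per library at PD0, 132386912 to 144057457 at PD2, 134347491 to 141718455 at PD4 and 128943323 to 150584371 at TPD4. The median barcode held 4132 to 10920.5 UMIs and 1871 to 3304 genes. Some libraries stood apart. Cells of no named class made up 44.17% of PD2 replicate 3 (median 2514 UMIs) and 33.35% of PD4 replicate 2 (median 1083 UMIs), against 7.59 to 21.27% elsewhere. The mitochondrial limit removed 13.79 to 23.66% of barcodes in the 4 replicate 1 libraries and 4.98 to 18.88% in the other 8.

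Fibroblast-like cells (43564) and keratinocyte-like cells (42336) were the most numerous of the 16 classes, beside dermal papilla, dermal sheath, vascular, immune, pigment, nerve sheath, muscle and adipocyte classes. Fibroblast-like cells made up 44.4% ± 9.43 of cells at PD0, 38.4% ± 11.8 at PD2, 15.7% ± 11.2 at PD4 and 33.7% ± 11.3 at TPD4 (mean ± SD, n = 3 libraries). T or innate lymphoid-like cells made up 0.470% ± 0.103 at PD0, 1.44% ± 0.643 at PD2, 4.24% ± 3.80 at PD4 and 1.28% ± 0.329 at TPD4. Macrophage-like cells made up 0.487% ± 0.273 at PD0 and 0.939% ± 0.0987 at PD4. These PD4 and PD0 shares did not overlap in any of the 3 classes, each with the smallest possible exact permutation p = 0.1, and no share passed adjustment over 68 tests (lowest adjusted p = 0.697). PD4 replicate 2 held 6.83% fibroblast-like, 8.57% T or innate lymphoid-like and 5.54% dendritic or Langerhans-like cells. Shares also depend on dissociation and on the mixing of dermal with epidermal cells.

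**Figure D1:**
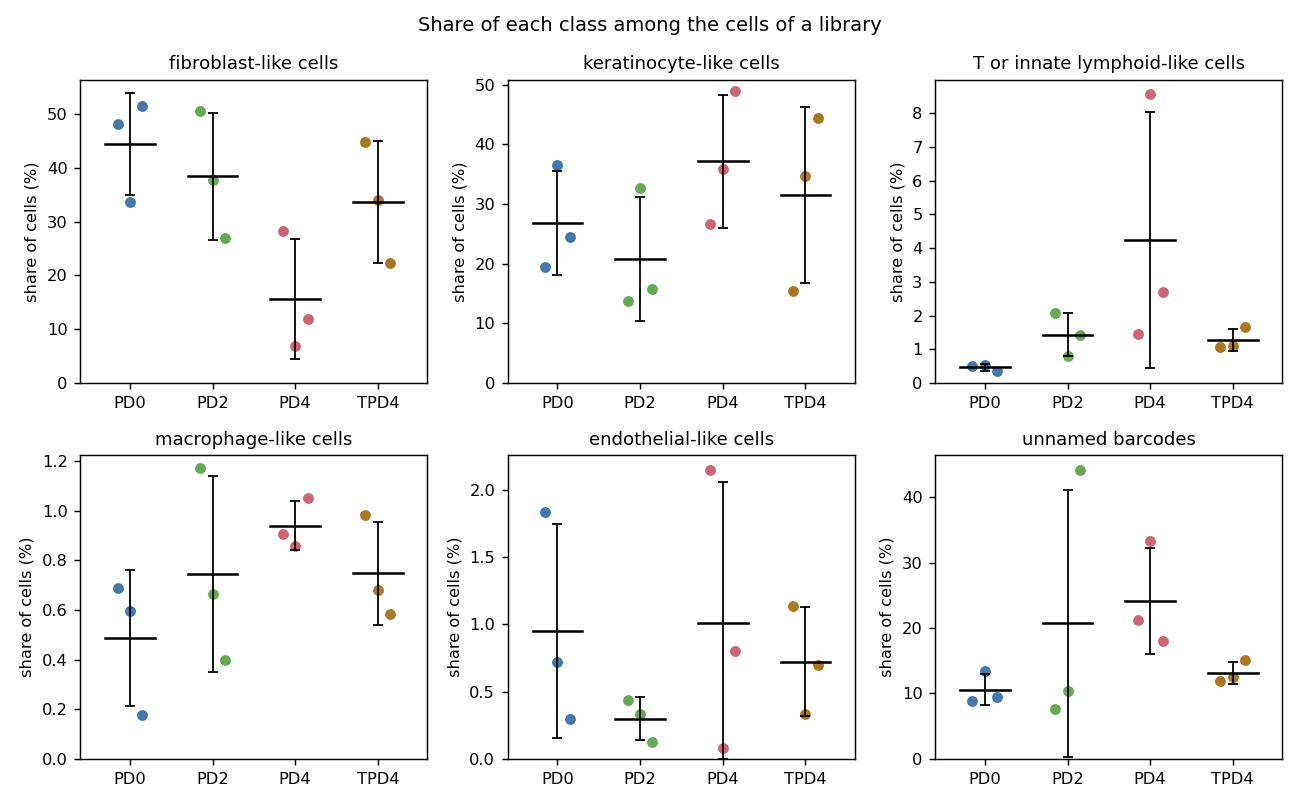
Share of 6 classes among the cells of each library (%), by group. Each point is 1 library, lines are means and bars are SD (n = 3, drawn down to 0 at most); fibroblast-like means are 44.4% at PD0 and 15.7% at PD4.

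The comparison of PD4 with PD0 asks how fibroblasts of the dermis change over the first days of life. Ccn5, a matricellular protein of the CCN family, rose from 2.09 ± 1.45 to 34.4 ± 16.8 CPM (n = 3 libraries each), a log2 change of 4.05 (SE 0.54, adjusted p = 0.000513). Hmcn2, an extracellular hemicentin, rose from 2.45 ± 0.998 to 27.8 ± 4.61 CPM, and Itgbl1, a secreted protein with integrin beta-like repeats, from 3.56 ± 3.17 to 38.7 ± 9.25 CPM. Pi16, a marker of adventitial and fascia fibroblasts, rose from 19.5 ± 10.2 to 174 ± 92.6 CPM, and Pcolce2, an enhancer of procollagen processing, from 6.38 ± 3.67 to 52.0 ± 26.4 CPM. Fmo2, a flavin monooxygenase, Col15a1, a basement membrane collagen, and Sfrp4, a secreted Wnt antagonist, completed the 8 largest rises, with log2 changes of 2.98, 2.71 and 2.61. Zbtb16, a zinc finger transcription factor, fell from 26.1 ± 10.8 to 2.77 ± 0.605 CPM, a log2 change of -3.27 (SE 0.31, adjusted p = 9.32e-05). Wif1, a secreted Wnt inhibitor, fell from 280.1 ± 35.7 to 52.5 ± 11.3 CPM, and Lef1, a transcription factor of the Wnt pathway, from 44.9 ± 8.45 to 10.3 ± 3.12 CPM. The agouti gene a, whose product switches hair pigment type, fell from 239 ± 15.04 to 55.4 ± 12.4 CPM. Cntn4, a contactin, Eva1a, Runx3, a Runt family transcription factor, and Pappa2, a protease of insulin-like growth factor binding proteins, fell by 2.90, 2.88, 2.13 and 2.08 on the log2 scale. The identifiers of the main genes are ENSMUSG00000027656 for Ccn5 (mm10 chromosome 2, 163820861 to 163833146), ENSMUSG00000024011 for Pi16 (chromosome 17, 29317680 to 29330593), ENSMUSG00000020218 for Wif1 (chromosome 10, 121033960 to 121100650) and ENSMUSG00000027985 for Lef1 (chromosome 3, 131110471 to 131224356), all annotated as protein-coding.

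Among the 13 genes always given, Cdkn1a, an inhibitor of cyclin-dependent kinases, fell from 76.2 ± 15.7 to 30.3 ± 3.58 CPM between PD0 and PD4 in fibroblast-like cells (log2 change -1.33, adjusted p = 0.000402, n = 3). Beside Lef1, the other 11 did not pass. The imprinted genes H19, Dlk1, Mest and Igf2 had log2 changes of 0.70 (adjusted p = 0.0528), -0.75 (0.0568), 0.49 (0.065) and 0.79 (0.18). The collagens Col1a1 and Col3a1 had changes of 0.16 and 0.20, Crabp1, a retinoic acid binding protein, -0.22, the proliferation marker Mki67 -0.11 and the linker histone gene H1f0 -0.45. The histone deacetylases Hdac1 and Hdac2 had changes of 0.33 (adjusted p = 0.0632) and 0.30 (0.061).

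**Figure D2:**
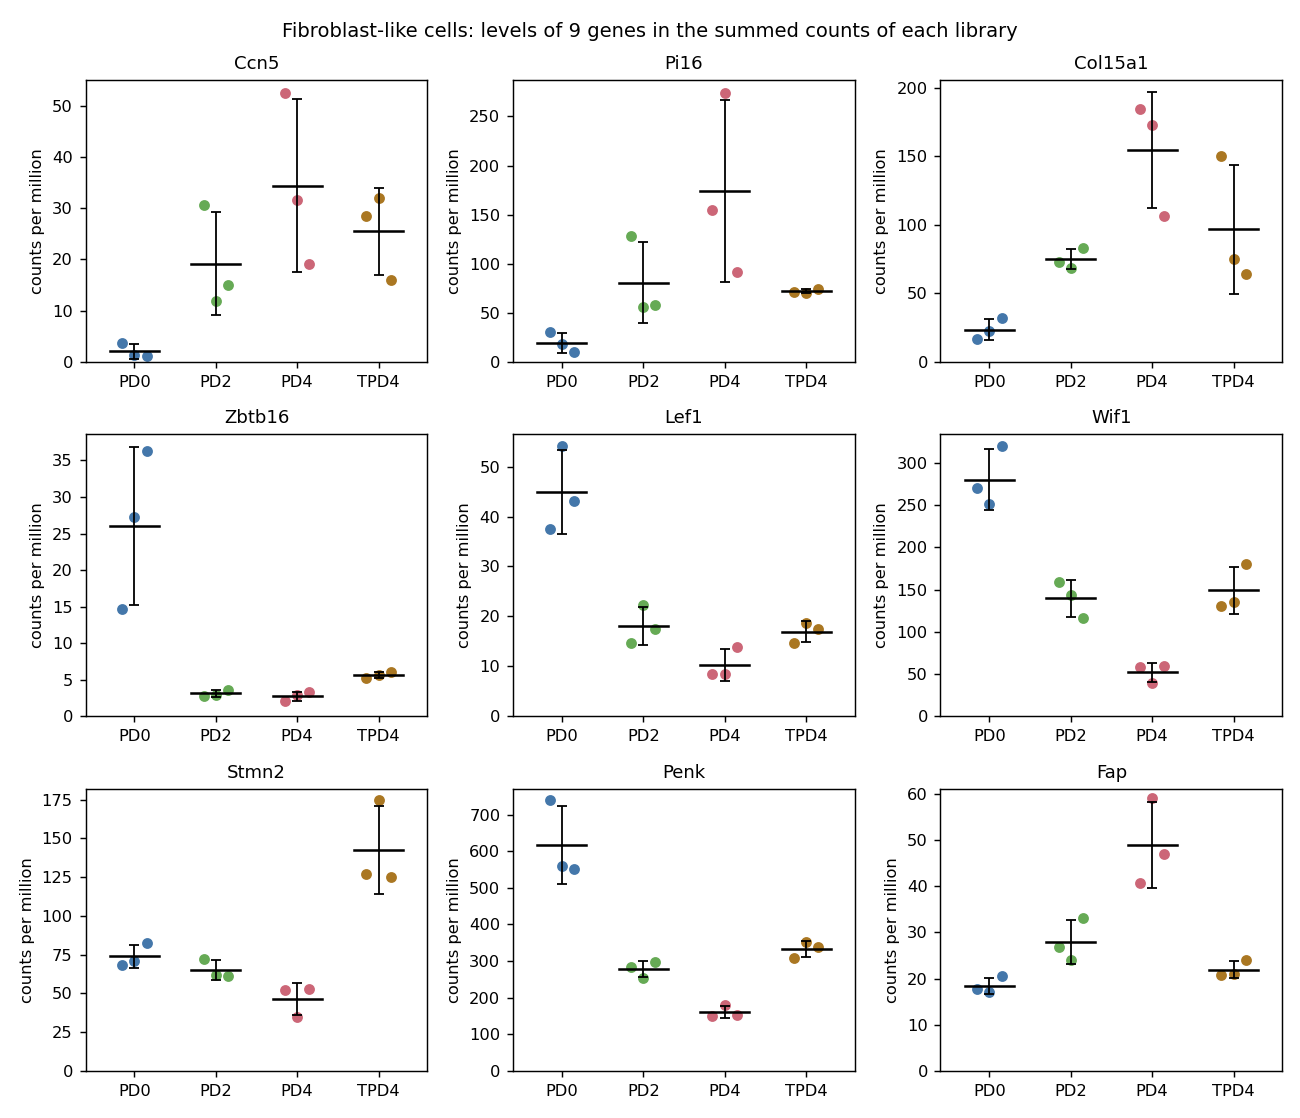
Levels of 9 genes in fibroblast-like cells, in CPM of the summed counts of each library, by group. Each point is 1 library, lines are means and bars are SD (n = 3, drawn down to 0 at most); mean Wif1 was 280.1 CPM at PD0, 52.5 at PD4 and 149 at TPD4.

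Gene groups moved in both directions in fibroblast-like cells from PD0 to PD4. Of 17 measured canonical Wnt targets, 8 fell, 1 rose and 8 did not pass, or 13 fell and 1 rose when adjusted over the list alone. Dkk1, a secreted Wnt antagonist, fell from 55.6 ± 5.47 to 14.95 ± 4.19 CPM, while its relative Dkk2 rose from 27.1 ± 3.19 to 127 ± 27.1 CPM. The camera call for these targets (adjusted p = 2.6e-07) was lost with an estimated correlation (adjusted p = 0.363). Of 17 papillary fibroblast genes, 5 fell, among them Col23a1 from 80.8 ± 6.53 to 26.9 ± 11.6 CPM, 2 rose, among them Col18a1 from 21.2 ± 2.60 to 45.0 ± 2.36 CPM, and 10 did not pass (8 fell and 3 rose adjusted over the list alone; adjusted p = 0.377 with an estimated correlation). Of 17 reticular and fascia genes, 10 rose and 7 did not pass (11 rose and 1 fell adjusted over the list alone). Sema3c, a secreted semaphorin, rose from 51.4 ± 16.6 to 235 ± 129.97 CPM, and Cd34, a sialomucin of dermal fibroblasts, from 288.5 ± 22.8 to 483 ± 77.4 CPM. That list had an adjusted p of 1.2e-05 by camera and of 0.447 with an estimated correlation.

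Some matrix genes rose over the same interval in fibroblast-like cells. Of 33 genes of elastic fibres and other matrix, 15 rose, 2 fell and 16 did not pass, with 18 and 2 adjusted over the list alone (adjusted p = 0.377 with an estimated correlation). Mfap4, a microfibril-associated protein, rose from 808 ± 35.5 to 3460.3 ± 1324.5 CPM, Prelp, a leucine-rich proteoglycan, from 11.4 ± 2.79 to 33.6 ± 7.30 CPM, and Ltbp2, a latent TGF-beta binding protein family member, from 33.8 ± 2.24 to 85.3 ± 19.1 CPM. Of 30 genes of fibrillar collagens and their processing, 6 rose and 24 did not pass, with the same numbers adjusted over the list alone (adjusted p = 0.616 with an estimated correlation). Loxl3, a lysyl oxidase, Col5a3, a fibrillar collagen chain, and P3h4, of the collagen prolyl 3-hydroxylase family, had log2 changes of 1.54, 1.46 and 0.72. Of 11 complement genes, 6 rose and 5 did not pass, and 6 rose adjusted over the list alone (adjusted p = 0.363 with an estimated correlation). They included C1s1 (12.7 ± 3.26 to 37.5 ± 10.9 CPM), Serping1, an inhibitor of C1 (86.4 ± 21.04 to 251 ± 61.2 CPM), and Cd55 (log2 change 1.16), whose product restrains complement.

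Regulators of growth and chromatin split by member in fibroblast-like cells. Of 20 genes of the insulin-like growth factor axis, 5 rose, 6 fell and 9 did not pass, with 6 and 6 adjusted over the list alone. Its median (0.22) and mean (0.12) were positive while camera ranked it down (adjusted p = 0.785, and 0.886 with an estimated correlation). Igf2bp3, an RNA-binding protein of fetal tissue, fell from 39.1 ± 1.09 to 15.8 ± 1.29 CPM. Igfbp7 rose from 120.5 ± 15.2 to 368 ± 75.0 CPM, and Stc2, a stanniocalcin, from 2.05 ± 0.128 to 7.375 ± 1.89 CPM. Of 34 genes of chromatin remodelling complexes, 6 fell, 1 rose and 27 did not pass, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.035, and 0.749 with an estimated correlation). Hmga2, a high-mobility group protein of embryonic tissue, fell from 15.6 ± 5.75 to 3.30 ± 0.346 CPM, Arid2, of the PBAF complex, from 79.6 ± 13.2 to 46.3 ± 1.98 CPM, and Smarce1 from 142 ± 21.7 to 94.2 ± 8.33 CPM, while Smarcd3 rose from 11.3 ± 1.68 to 19.2 ± 7.86 CPM. Of 17 histone deacetylases and sirtuins, Hdac5 alone fell (log2 change -0.83, adjusted p = 0.00254), as it did adjusted over the list alone (adjusted p = 0.749 with an estimated correlation), and Sirt1 did not pass (-0.43). Of 36 cell cycle genes, Cenpa, a centromeric histone, alone fell (102.5 ± 34.2 to 58.7 ± 10.2 CPM), and none passed adjusted over the list alone (adjusted p = 0.818 with an estimated correlation). None of 18 imprinted growth genes passed in edgeR over all genes or adjusted over the list alone (adjusted p = 0.818 with an estimated correlation), Zim1 among them at 0.59. Of 18 chemokines and cytokines, 3 rose and 1 fell, with the same numbers adjusted over the list alone (adjusted p = 0.749 with an estimated correlation). Ccl11, an eosinophil attractant, rose from 7.69 ± 2.38 to 41.0 ± 3.45 CPM and Il33, an alarmin, from 2.19 ± 0.559 to 8.33 ± 2.31 CPM. Cxcl14 fell from 120 ± 24.2 to 52.2 ± 14.6 CPM, and Ccl8 rose to 0.664 CPM against 272 CPM in macrophage-like cells.

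**Figure D3:**
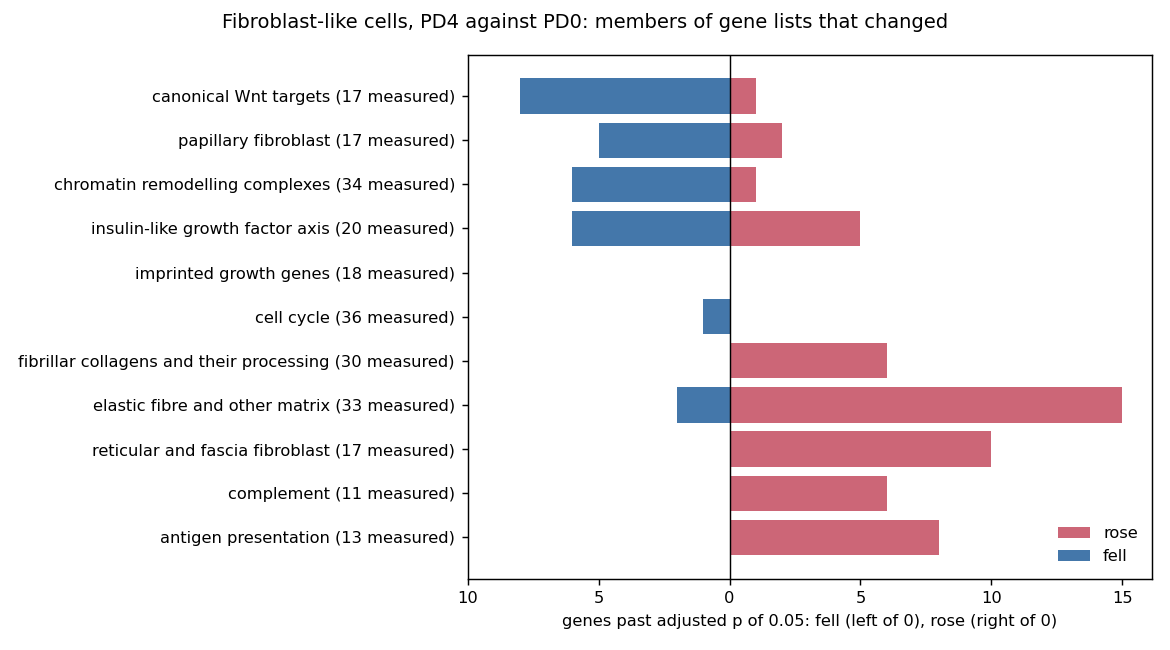
Members of 11 gene lists that changed in fibroblast-like cells, PD4 against PD0. Bars count genes past an adjusted p of 0.05 that fell (left of 0) or rose (right of 0), and the number measured follows each name; canonical Wnt targets show 8 falls and 1 rise, elastic fibre and other matrix 15 rises and 2 falls.

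Markers of other cells moved with age in the fibroblast-like sums too. Of 13 leukocyte markers, 6 rose (8 adjusted over the list alone), among them Cd74 from 3.06 ± 0.568 to 29.5 ± 21.03 CPM, Cd3g from 0.507 ± 0.242 to 12.8 ± 12.1, Cd52 with a log2 change of 2.50 and Cd3e with 5.01. The call for Cd3e was lost without PD4 replicate 2. Of 13 antigen presentation genes, 8 rose (8 adjusted over the list alone; adjusted p = 0.363 with an estimated correlation). H2-D1 rose from 33.4 ± 8.83 to 84.1 ± 8.42 CPM, and H2-Aa and H2-Eb1, class II genes, to 14.7 ± 12.6 and 10.8 ± 8.23 CPM, against 135 and 86.7 CPM in macrophage-like cells. Of 23 genes of hair follicle epithelium, 12 rose and 1 fell (13 and 2 adjusted over the list alone), and of 18 genes of epidermal differentiation 8 rose (9 adjusted over the list alone). Members of these lists with small adjusted p values had log2 changes as follows: Krt25 (5.90), Tgm3 (4.83), Mt4 (4.28), Klk7 (3.53), Hoxc13 (3.22), Sprr1a (3.11) and Dlx3 (2.42). Tgm3 stood at 4.09 CPM at PD4, against 67.5 CPM over all keratinocyte-like cells. Of 10 melanocyte markers 5 rose and 1 fell (6 and 1 adjusted over the list alone), with Tyrp1, Mlana, Dct and Pmel at 2.71, 2.13, 1.60 and 1.33. Of 12 markers of pericytes and smooth muscle 5 rose (8 rose and 1 fell adjusted over the list alone), with Acta2, Mustn1, Des and Abcc9 at 1.22, 1.63, 1.69 and 1.01. Of 9 mast cell markers 5 fell (8 adjusted over the list alone), with Hdc, Tpsab1, Kit and Cpa3 at -2.48, -4.85, -1.42 and -1.26. With an estimated correlation these 6 marker lists had adjusted p values of 0.616 for leukocytes, 0.372 for hair follicle epithelium, 0.377 for epidermal differentiation, 0.446 for melanocytes, 0.363 for pericytes and smooth muscle, and 0.447 for mast cells.

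In all, 3433 of 15831 genes changed between PD0 and PD4 in fibroblast-like cells, 1769 up and 1664 down (4017 by DESeq2). Groups did not overlap for 95.5% of changed genes and for 34.2% of all tested, against 10% by chance. The count was 2205 without PD4 replicate 2, and 260 of the changed genes, 225 of them rises, stood below 1/10 of their level in another tested class. The cells themselves lay in different clusters. Cluster 2 held 47.4% of fibroblast-like cells at PD0 and 0.422% at PD4, and clusters 5 and 11 held 0.905 and 1.62% at PD0 and 27.5 and 16.7% at PD4.

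The comparison of PD2 with PD0 covers the first part of this interval. Of the 3433 genes changed from PD0 to PD4, 1488 also passed from PD0 to PD2, in comparisons that share the PD0 libraries. From PD0 to PD2, Pi16 rose from 19.5 ± 10.2 to 80.9 ± 40.9 CPM, Pcolce2 from 6.38 ± 3.67 to 21.2 ± 9.53, Col15a1 from 23.7 ± 7.70 to 75.0 ± 7.39, Mfap4 from 808 ± 35.5 to 2421 ± 384 and Ccl11 from 7.69 ± 2.38 to 22.6 ± 7.64 CPM (n = 3 libraries each). Zbtb16 fell from 26.1 ± 10.8 to 3.16 ± 0.455 CPM, Eva1a from 34.0 ± 9.005 to 7.83 ± 0.801, Pappa2 from 49.5 ± 7.76 to 12.9 ± 3.56, Per1, a clock gene, from 51.0 ± 23.3 to 13.85 ± 5.40, and Cirbp, a cold-inducible RNA-binding protein, from 312 ± 13.6 to 96.5 ± 4.60 CPM. Lef1 and Cdkn1a fell (log2 changes -1.31 and -0.55), Hdac1 rose from 61.0 ± 7.48 to 87.8 ± 6.31 CPM and Hdac2 from 71.6 ± 4.13 to 96.3 ± 6.14 CPM. Dlk1, H19, Igf2, Mest, Crabp1, Col1a1, Col3a1, Mki67 and H1f0 did not pass, with log2 changes between -0.42 and 0.36.

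By list, fibroblast-like cells from PD0 to PD2 showed 4 rises and 13 genes not passing among 17 reticular and fascia genes (7 rises adjusted over the list alone), with Dact2, Sema3c and Cd55 at 3.02, 1.34 and 0.86. Of 33 elastic fibre and other matrix genes 4 rose and 2 fell (6 and 2 adjusted over the list alone), among them Ltbp2 (0.73) and Fbln1, a fibulin (-0.61). Of 20 genes of the insulin-like growth factor axis 2 rose and 6 fell (4 and 7 adjusted over the list alone), with Igf2bp3, Igf2bp2 and Stc2 at -1.15, -0.76 and 1.43. Of 34 genes of chromatin remodelling complexes 1 rose and 6 fell (2 and 7 adjusted over the list alone), with Hmga2, Hmga1, Arid2 and Smarcd3 at -1.59, -1.61, -0.68 and 1.01. Of 17 histone deacetylases and sirtuins, Hdac1 and Hdac2 rose and Hdac5 fell (-0.61), also adjusted over the list alone, and Sirt1 did not pass (-0.41). Of 17 canonical Wnt targets 1 rose and 3 fell (1 and 4 adjusted over the list alone), Wif1 from 280.1 ± 35.7 to 140.1 ± 21.9 CPM, Dkk1 with a change of -0.64 and Dkk2 with a rise of 1.44. Of 36 cell cycle genes Cdc6 alone rose (0.75) and none passed adjusted over the list alone; Mcm2, Rrm2 and Tyms had changes of 0.48, 0.67 and 0.67. Of 11 complement genes 2 rose (4 adjusted over the list alone), C1s1 with 0.72 beside Cd55, while Serping1 (0.70) did not pass over all genes. Antigen presentation gave 4 rises among 13 (5 adjusted over the list alone), H2-D1 with 0.76 and Cd74, H2-Eb1 and H2-Aa with 1.93, 1.85 and 1.79, each of these 3 below 1/10 of its level in macrophage-like cells. Among markers of other cells, 3 of 9 for mast cells fell (4 adjusted over the list alone), Tpsab1, Hdc and Kit at -2.82, -1.70 and -0.91. Acta2 and Des, markers of pericytes and smooth muscle, rose by 1.253 and 1.41 (2 of 12, and 4 adjusted over the list alone). Of 13 leukocyte markers Cd74 alone rose, and 4 rose adjusted over the list alone; Lyz2, Cd52 and Cd3g had changes of 1.00, 1.28 and 2.26 and did not pass over all genes. Every one of these lists had an adjusted p of 0.982 with an estimated correlation except pericytes and smooth muscle (0.701).

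Between PD0 and PD2, 1901 of 15831 genes changed in fibroblast-like cells, 916 up and 985 down (2671 by DESeq2), and 3453 with the replicate number as a block. Only 2 of these libraries correlated best with their own replicate number in the other group. Groups did not overlap for 99.3% of changed and 32.9% of tested genes, against 10% by chance. The count was 893 without PD0 replicate 2, and 825, 833 and 897 without PD2 replicates 1, 2 and 3. It held 75 genes below 1/10 of their level in another tested class. Cells were again in different clusters, with clusters 0 and 5 the largest at PD2 (22.9 and 23.6%).

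From PD2 to PD4 few genes passed. Wif1 fell from 140.1 ± 21.9 to 52.5 ± 11.3 CPM (n = 3, log2 change -1.41, SE 0.19, adjusted p = 0.028) and Dkk1 from 35.6 ± 6.85 to 14.95 ± 4.19 CPM (-1.26, SE 0.19, adjusted p = 0.0434). The other 6 lay outside the naming rule and are named after their values were seen. Ntsr1, a neurotensin receptor, fell from 1.89 ± 0.0688 to 0.259 ± 0.0448 CPM. Hoxc13, a homeobox factor of hair, Gjb2, a gap junction protein, Defb1, a defensin, Tgm3, an epidermal transglutaminase, and Mt2, a metallothionein, rose by 2.65, 2.65, 2.59, 2.34 and 1.81 on the log2 scale. These 5 were highest in clusters other than fibroblast-like ones, Hoxc13 and Gjb2 in the unnamed cluster 41 (426.6 and 290.4 CPM), Defb1 and Tgm3 in the keratinocyte-like clusters 34 and 3 (82.0 and 136 CPM) and Mt2 in the unnamed cluster 9 (3553 CPM). The 13 genes always given did not pass, with Cdkn1a at -0.78, Lef1 at -0.82, Hdac1 at -0.20, Hdac2 at -0.13, Igf2 at 0.57, H19 at 0.34, Mest at 0.25, Dlk1 at -0.33, Crabp1 at 0.08, Col1a1 at 0.16, Col3a1 at 0.25, Mki67 at -0.26 and H1f0 at -0.24.

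Lists in fibroblast-like cells between PD2 and PD4 moved mainly when tested alone. Canonical Wnt targets showed 2 falls among 17 (9 falls and 1 rise adjusted over the list alone), with Tcf7 at -0.81 and Nkd1 at -0.80 (adjusted p = 0.124 with an estimated correlation). Hair follicle epithelium showed 1 rise among 23 (10 rises and 1 fall adjusted over the list alone), with Krt73, Krt27 and Krt25, inner root sheath keratins of 1.32, 2.70 and 10.2 CPM at PD4 that did not pass over all genes (adjusted p = 0.124 with an estimated correlation). None of 33 elastic fibre and other matrix genes passed over all genes and 8 rose adjusted over the list alone, among them Ogn (0.89) and Prelp (0.89), and Col14a1 and Col15a1 had changes of 0.95 and 1.05 (adjusted p = 0.243 with an estimated correlation). None of 36 cell cycle genes passed over all genes and 5 fell adjusted over the list alone, with Mcm2, Mcm5, Mcm3 and Rrm2 at -0.67, -0.81, -0.75 and -0.84 (adjusted p = 0.279 with an estimated correlation). In all, 8 of 15831 genes changed, 5 up and 3 down (1785 at an unadjusted p under 0.05; 248 by DESeq2). No overlap between groups was seen for 16.5% of tested genes, against 10% by chance. The count was 0 without any 1 of PD2 replicates 1, 2 and 3 or PD4 replicate 1, 1 without PD4 replicate 3 and 17 without PD4 replicate 2.

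The comparison of TPD4 with PD4 asks what TSA does to these cells at the same age. In fibroblast-like cells Wif1 rose from 52.5 ± 11.3 CPM without to 149 ± 27.5 CPM with TSA (n = 3 libraries each; log2 change 1.502, SE 0.19, adjusted p = 0.00579). Stmn2, a regulator of microtubules in neurons, rose from 46.6 ± 10.3 to 142 ± 28.4 CPM (1.61, SE 0.18, adjusted p = 0.00427), Penk, the precursor of enkephalins, from 161 ± 17.2 to 334 ± 22.4 CPM (1.05, SE 0.14, adjusted p = 0.0113) and Plxna4, a semaphorin receptor, from 23.3 ± 2.27 to 45.1 ± 5.81 CPM. Fap, a serine protease of activated fibroblasts, fell from 48.9 ± 9.33 to 22.0 ± 1.82 CPM (-1.15, SE 0.16, adjusted p = 0.0143), Ssc5d, a scavenger receptor family protein, from 32.6 ± 10.8 to 10.4 ± 2.41 CPM and Cgref1, a secreted EF-hand protein, from 28.0 ± 8.95 to 6.32 ± 1.19 CPM. Stmn2 (ENSMUSG00000027500) lies on mm10 chromosome 3, 8509360 to 8561606, Penk (ENSMUSG00000045573) on chromosome 4, 4133531 to 4138819, and Fap (ENSMUSG00000000392) on chromosome 2, 62500943 to 62574075. The other 10 genes that changed were below the level the naming rule asks for, and 9 of them are named after their values were seen. Pcsk1n, Prss50, Sncb, Ntsr1, Kcns2 and Soga3 rose, to 7.49, 3.28, 14.9, 1.29, 5.98 and 9.84 CPM, by 4.18, 2.88, 2.81, 2.23, 2.14 and 2.05 on the log2 scale. Of these, Sncb encodes beta-synuclein and Kcns2 a potassium channel subunit. Wfdc1, Ptgds, a prostaglandin D2 synthase, and Lypd2 fell by 1.10, 1.67 and 2.48.

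In fibroblast-like cells given TSA, canonical Wnt targets showed 1 rise among 17 over all genes, and 9 rises and 1 fall adjusted over the list alone. Axin2, a feedback target of the pathway, stood at 55.9 ± 3.37 CPM against 34.1 ± 8.39, Dkk1 at 29.9 ± 2.79 against 14.95 ± 4.19 and Tcf7 at 32.8 ± 2.19 against 19.7 ± 4.12. The list had an adjusted p of 2.9e-16 by camera and 0.0997 with an estimated correlation. Papillary fibroblast genes showed 1 rise among 17 (4 rises and 1 fall adjusted over the list alone; adjusted p = 0.229 with an estimated correlation), with Lrig1 at 84.8 ± 7.29 against 56.5 ± 4.70 CPM. None of 33 elastic fibre and other matrix genes passed over all genes and 6 fell adjusted over the list alone (adjusted p = 0.235 with an estimated correlation), with Ogn, Ltbp2, Prelp and Postn at -0.94, -0.96, -0.97 and -1.03. None of 30 fibrillar collagen genes passed over all genes and 1 fell adjusted over the list alone (adjusted p = 0.235 with an estimated correlation), with Pcolce, P3h2, P3h4 and Col1a1 at -0.98, -0.73, -0.52 and -0.68. None of 11 complement genes passed over all genes and 4 fell adjusted over the list alone (adjusted p = 0.252 with an estimated correlation), with C2, Serping1 and Cfb at -0.82, -0.84 and -1.65. Of 16 matrix degradation genes Fap alone fell, and 2 fell adjusted over the list alone (adjusted p = 0.202 with an estimated correlation), with Ctsk, Timp2 and Mmp23 at -0.76, -0.44 and -0.73. Of 12 genes raised by histone deacetylase inhibitors in culture none passed over all genes and 1 rose adjusted over the list alone. That list had a median of -0.06, a mean of 0.02 and an upward rank in camera (adjusted p = 0.564, and 0.722 with an estimated correlation). Its members Cdkn1c, Cdkn1a, Gsn and Clu had changes of -0.49, 0.71, -0.42 and 0.60.

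None of 17 histone deacetylases and sirtuins and none of 34 genes of chromatin remodelling complexes passed in fibroblast-like cells given TSA, over all genes or adjusted over the list alone (adjusted p = 0.823 and 0.533 with an estimated correlation). Hdac9, Hdac5, Sirt2 and Hdac10 had changes of 0.39, -0.14, 0.15 and -0.17, and Arid1b, Smarce1, Ezh2 and Smarcd1 of 0.22, 0.22, 0.29 and 0.33. None of 36 cell cycle genes passed either way (adjusted p = 0.646 with an estimated correlation), with Mcm3, Hells, Mcm2 and Pcna at 0.41, 0.50, 0.28 and 0.32. The 13 genes always given did not pass, Lef1 at 0.73, Cdkn1a at 0.71, Mest at -0.61, Igf2 at -0.64, H19 at -0.34, Dlk1 at 0.04, Crabp1 at -0.45, Col1a1 at -0.68, Col3a1 at -0.43, Mki67 at 0.17, H1f0 at 0.18, Hdac1 at 0.08 and Hdac2 at 0.02. Leukocyte markers moved with the treatment in these sums. None of 13 passed over all genes and 11 fell adjusted over the list alone (adjusted p = 0.235 with an estimated correlation), with Lyz2, Cd52, Cd3g and Fcer1g at -1.44, -2.01, -2.78 and -1.55.

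In all, 17 of 15831 genes changed with TSA in fibroblast-like cells, 11 up and 6 down (1249 at an unadjusted p under 0.05; 155 by DESeq2). With the replicate number as a block 69 changed, and the 17 were among them. Groups did not overlap for all 17 and for 11.9% of tested genes, against 10% by chance. The count was 9 without PD4 replicate 1, PD4 replicate 2 or TPD4 replicate 1, 6 without TPD4 replicate 2 and 8 without TPD4 replicate 3. None of the 17 stood below 1/10 of its level in another tested class, but 3 stood below 1/10 of their level in a cluster of a class not tested, Ptgds in the melanocyte-like cluster 27 (4079 CPM), Pcsk1n in the dermal papilla or condensate-like cluster 13 (35.8 CPM) and Kcns2 in the dermal sheath or myofibroblast-like cluster 30 (47.2 CPM). Wif1 and Stmn2 stood just above that bound, at means of 151.9 and 82.16 CPM over all libraries. Wif1 reached 1518 CPM in cluster 13 and Stmn2 752.2 CPM in the dermal sheath or myofibroblast-like cluster 25. At PD4 alone they stood at 52.5 and 46.6 CPM, below 1/10 of those levels.

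The change with TSA was set against the change with age across the 15831 genes tested in fibroblast-like cells. Of the 17 genes that changed with TSA, 14 had the opposite sign from PD0 to PD2, of which 9 passed there, and the other 3 did not pass there. Stmn2 was among the 14 with a log2 change of -0.18 (adjusted p = 0.547). Among the 9, Penk fell from 617.6 to 279.1 CPM and Fap rose from 18.45 to 27.99 CPM between PD0 and PD2 (adjusted p = 0.00124 and 0.0297), the reverse of their changes with TSA. Log2 changes with TSA and from PD0 to PD2, which share no library, had a Pearson r of -0.214 (Spearman rho -0.189) across genes, which are not independent replicates. In 20 simulations with no TSA or age effect the mean r was -0.00485, between -0.0294 and 0.0261. Real libraries split otherwise reached 0.159 in size, far outside that range, so it cannot gauge chance alone. Among the 10 ways to split the PD4 and TPD4 libraries, the real one had the largest r in size, so the exact permutation p is 0.1, the smallest possible. Only 4 of them part all 3 same-numbered pairs, which allows no p under 0.25, and the largest in size of the other 3 was -0.133. Leaving out each library in turn gave -0.149 to -0.259. Against the change from PD0 to PD4, which shares the PD4 libraries, r was -0.553, and simulation without any effect gave -0.579 (between -0.610 and -0.548). The covariance was -0.183 against a simulated -0.0717, a difference of -0.111, part of which may come from the shared controls.

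**Figure D4:**
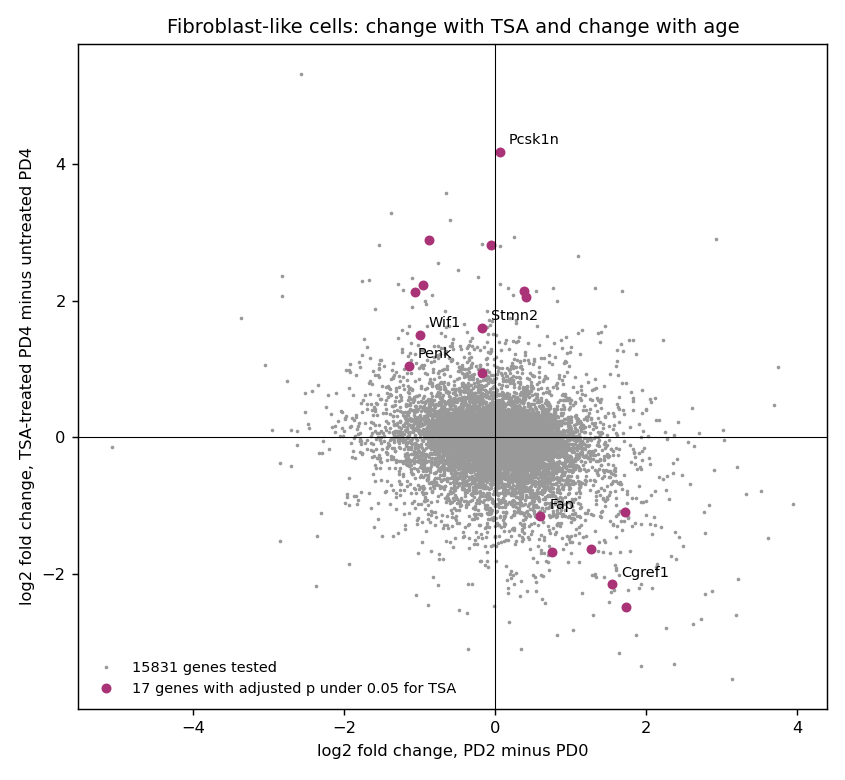
Log2 fold change with TSA (TPD4 minus PD4, vertical) against log2 fold change with age (PD2 minus PD0, horizontal) in fibroblast-like cells. Each grey point is 1 of 15831 genes tested, and the 17 larger points are genes with an adjusted p under 0.05 for TSA; r across genes was -0.214.

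Keratinocyte-like cells were compared between PD4 and PD0 to ask which changes with age lie outside the fibroblasts. Tgm3, a transglutaminase of the hair shaft and epidermal barrier, rose from 3.13 ± 0.502 to 158 ± 20.6 CPM (n = 3 libraries each; log2 change 5.67, SE 0.20, adjusted p = 7.3e-09). Fcgbp rose from 1.32 ± 0.158 to 34.9 ± 5.40 CPM, Mt4, a metallothionein of stratified epithelium, from 1.89 ± 0.918 to 41.3 ± 12.8, Pdzrn4 from 1.35 ± 0.732 to 27.8 ± 7.37 and Krt77, a suprabasal keratin, from 3.83 ± 2.05 to 70.2 ± 26.1 CPM. Zbtb16 fell from 33.9 ± 14.7 to 2.41 ± 0.681 CPM, Fkbp5, a co-chaperone of the glucocorticoid receptor, from 37.1 ± 19.3 to 3.08 ± 0.298, Col27a1 from 51.05 ± 8.86 to 6.65 ± 1.02 and N4bp2l1 from 27.9 ± 8.48 to 4.70 ± 0.900 CPM. Tgm3 (ENSMUSG00000027401) lies on mm10 chromosome 2, 130012349 to 130050399.

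By list, epidermal differentiation genes in keratinocyte-like cells showed 11 rises and 1 fall among 25 from PD0 to PD4 (11 and 2 adjusted over the list alone; adjusted p = 0.591 with an estimated correlation), with Klk5, a serine protease of desquamation, at 1.477 and Sprr1a at 2.27. Genes of hair follicle epithelium split, with 5 rises, 6 falls and 15 not passing among 26 (10 and 7 adjusted over the list alone). Their median (0.14) and mean (0.12) were positive while camera ranked them down (adjusted p = 0.524, and 0.892 with an estimated correlation). Edar, the ectodysplasin receptor, fell from 12.1 ± 2.41 to 2.12 ± 0.248 CPM, Wnt10b from 75.6 ± 10.5 to 24.8 ± 5.62 and Shh, sonic hedgehog, from 16.2 ± 7.89 to 2.58 ± 1.249 CPM, genes of early follicle formation, while Krt25 rose by 5.42. Canonical Wnt targets showed 9 falls among 17 (10 falls and 2 rises adjusted over the list alone; adjusted p = 0.552 with an estimated correlation), with Lef1, Tcf7, Nkd1 and Sp5 at -1.82, -0.99, -1.70 and -2.61. Of 16 basal keratinocyte genes 5 fell and 1 rose, as adjusted over the list alone (adjusted p = 0.809 with an estimated correlation), Cdh3, Itgb4 and Lamb3, genes of cell adhesion, with -0.93, -0.72 and -0.56, and Krt15, a basal keratin, from 5016 ± 974 to 8302 ± 587 CPM. Of 21 genes of hypoxia and glycolysis 9 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.591 with an estimated correlation), Pfkp, a phosphofructokinase, with 1.73, Hk1, a hexokinase, with 1.17, Car9 with 3.03 and Egln3 with 1.10. Of 28 genes of oxidative phosphorylation 11 rose (13 adjusted over the list alone; adjusted p = 0.837 with an estimated correlation), Ndufa1, Uqcrq, Ndufb2 and Ndufa5 with 0.73, 0.69, 0.72 and 0.60. Of 36 cell cycle genes 7 rose (6 adjusted over the list alone; adjusted p = 0.809 with an estimated correlation), Ccna2, Tyms, Bub1b and Cdc6 with 0.86, 0.76, 0.61 and 0.58. Of 18 imprinted growth genes 7 fell and 1 rose, as adjusted over the list alone (adjusted p = 0.591 with an estimated correlation), Dlk1, Grb10, Sgce and Zdbf2 with -1.92, -1.36, -0.83 and -1.38, Dlk1 at 6.04 CPM at PD4 against 1288 CPM in fibroblast-like cells.

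Markers of other cells moved with age in keratinocyte-like sums as well. Of 14 antigen presentation genes 6 rose (7 adjusted over the list alone; adjusted p = 0.591 with an estimated correlation), with H2-K1, H2-Eb1, H2-Aa and H2-Ab1 at 1.66, 2.80, 3.52 and 2.42, each below 1/10 of its level in macrophage-like cells. Of 13 leukocyte markers 5 rose (7 adjusted over the list alone), with Cd74, Lyz2, Cd3g and Cd52 at 2.50, 1.58, 4.32 and 2.20. Of 10 melanocyte markers 7 rose (8 adjusted over the list alone), with Tyrp1, Dct, Pmel and Mlana at 3.005, 1.67, 1.37 and 1.95. Of 12 fibroblast markers 4 fell (4 adjusted over the list alone), Dcn from 696 ± 34.5 to 121 ± 2.39 CPM against 4944 CPM in fibroblast-like cells, and Pdgfra, Twist2 and Col6a3 with -1.31, -1.71 and -0.93. Of 9 mast cell markers 4 fell (4 adjusted over the list alone), with Tpsab1, Hdc, Cpa3 and Tpsb2 at -5.96, -2.60, -1.22 and -1.47. With an estimated correlation the adjusted p was 0.591 for melanocyte markers and 0.809 for leukocyte, fibroblast and mast cell markers.

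In all, 3784 of 15856 genes changed between PD0 and PD4 in keratinocyte-like cells, 1935 up and 1849 down (4207 by DESeq2). Groups did not overlap for 96.3% of changed and 36.1% of tested genes, against 10% by chance. The count was 2371 without PD0 replicate 2, and it held 389 genes below 1/10 of their level in another tested class. Cluster 1 held 39.5% of these cells at PD0 and 13.8% at PD4, and cluster 3 held 13.4 and 24.7%. Mt4 and Krt25 were among the leading genes of the unnamed clusters 9 and 41, which the 1/10 check did not cover. Before doublet removal cluster 9 held 48, 78 and 77 cells in the PD0 libraries and 1433, 899 and 875 in the PD4 libraries. Cluster 41 held 5, 7 and 11, and 272, 33 and 89. RNA from these clusters in the keratinocyte-like sums was not tested.

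TPD4 was also compared with PD4 in keratinocyte-like cells. Ptch1, the main hedgehog receptor, rose from 65.6 ± 13.4 to 135 ± 12.2 CPM (n = 3 libraries each; log2 change 1.04, SE 0.16, adjusted p = 0.0137). Nrp2, a neuropilin, rose from 19.3 ± 2.28 to 41.7 ± 12.1, Grasp, a scaffold protein, from 19.1 ± 1.81 to 38.5 ± 8.51 and Kif26a, a kinesin, from 15.9 ± 3.35 to 32.2 ± 2.54 CPM. Tgm3 fell from 158 ± 20.6 to 53.4 ± 7.54 CPM (-1.56, SE 0.17, adjusted p = 0.00264). Fcgbp fell from 34.9 ± 5.40 to 11.3 ± 7.17, Il1r2, a decoy receptor of interleukin 1, from 34.8 ± 14.3 to 12.2 ± 4.01, Foxq1, a forkhead factor of hair, from 29.3 ± 5.603 to 11.6 ± 0.320 and Pglyrp4, a peptidoglycan recognition protein, from 23.1 ± 5.93 to 9.38 ± 2.63 CPM.

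Few members of the lists passed over all genes in keratinocyte-like cells given TSA. None of 17 canonical Wnt targets passed over all genes and 4 rose adjusted over the list alone (camera adjusted p = 4.5e-07, and 0.191 with an estimated correlation), with Lef1, Sp5, Nkd1 and Twist1 at 1.00, 1.65, 1.08 and 1.30. Of 26 genes of hair follicle epithelium Edar alone rose (1.02; 3 rose adjusted over the list alone), with Lgr6, a stem cell receptor, at 0.72 and Shh at 1.70. Of 20 genes of dermal papilla and condensate Ptch1 alone rose (4 rose adjusted over the list alone), with Prdm1 and Trps1 at 0.74 and 0.51. Of 25 epidermal differentiation genes Tgm3 alone fell (3 fell adjusted over the list alone; adjusted p = 0.820 with an estimated correlation), with Klk5 and Dsc1 at -1.003 and 0.85 and Sprr2d at 0.213 CPM or less. Of 21 genes of the interferon response Ifi27l2a and Usp18 fell by 0.94 and 2.24 (3 fell adjusted over the list alone), and Psmb9 and H2-D1 had changes of -0.77 and -0.43. None of 14 antigen presentation genes passed over all genes and 3 fell adjusted over the list alone, with Cd86, Cd74 and H2-Aa at -2.01, -1.31 and -1.34. None of 12 genes raised by histone deacetylase inhibitors in culture passed over all genes, and 1 rose and 1 fell adjusted over the list alone (adjusted p = 0.820 with an estimated correlation), with Tubb3, Sat1, Cdkn1c and Cdkn1a at 1.59, -0.58, -0.47 and -0.32. None of 13 leukocyte markers passed over all genes and 11 fell adjusted over the list alone, with Lyz2, Fcer1g and Tyrobp at -1.24, -1.51 and -1.24. None of 12 fibroblast markers passed over all genes or adjusted over the list alone, although all 12 had positive changes, Dcn, Twist2, Pdgfra and Fbn1 with 0.62, 1.252, 0.94 and 0.59. With an estimated correlation the lists of hair follicle epithelium, dermal papilla, interferon response, antigen presentation, leukocytes and fibroblasts had an adjusted p of 0.553.

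In all, 72 of 15856 genes changed with TSA in keratinocyte-like cells, 25 up and 47 down (1542 at an unadjusted p under 0.05; 315 by DESeq2). Groups did not overlap for 15.6% of tested genes, against 10% by chance, and 11 of the 72 stood below 1/10 of their level in another tested class. The count was 43, 22 and 24 without PD4 replicates 1, 2 and 3, and 10 and 20 without TPD4 replicates 2 and 3. The unnamed clusters 9 and 41 lie outside the 1/10 check. Before doublet removal they held 600, 289 and 311, and 52, 27 and 23 cells in the TPD4 libraries (PD4 above).

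A test of whether TSA acted differently on fibroblast-like and keratinocyte-like cells found 5 of 16225 genes past an adjusted p of 0.05 (1690 at an unadjusted p under 0.05; 168 by DESeq2). These 5 lay outside the naming rule, and 4 of them are named after their values were seen. Col27a1, a fibrillar collagen chain, rose from 6.65 ± 1.02 to 16.0 ± 1.99 CPM in keratinocyte-like cells and changed by -0.11 in fibroblast-like cells, a difference of -1.37 (SE 0.12, adjusted p = 0.00917). Ltbp2 stood at 85.3 ± 19.1 without and 43.9 ± 11.97 CPM with TSA in fibroblast-like cells and at 0.904 ± 0.210 and 1.39 ± 0.267 in keratinocyte-like cells, a difference of -1.62 (adjusted p = 0.00917). Thsd4, a thrombospondin-repeat protein of microfibrils, fell from 3.25 ± 0.420 to 1.12 ± 0.244 CPM in keratinocyte-like cells and stood at 34.2 ± 4.93 and 34.9 ± 3.84 in fibroblast-like cells, a difference of 1.62 (adjusted p = 0.00992). Pappa, a protease of insulin-like growth factor binding proteins, stood at 5.90 ± 0.691 and 2.91 ± 0.687 CPM in keratinocyte-like cells and at 45.7 ± 7.76 and 55.01 ± 11.6 in fibroblast-like cells, a difference of 1.30 (adjusted p = 0.00917). Col27a1 (ENSMUSG00000045672) lies on mm10 chromosome 4, 63214004 to 63334991. The count was 10 without PD4 replicate 1 and 0 without PD4 replicate 3, TPD4 replicate 2 or TPD4 replicate 3.

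**Figure D5:**
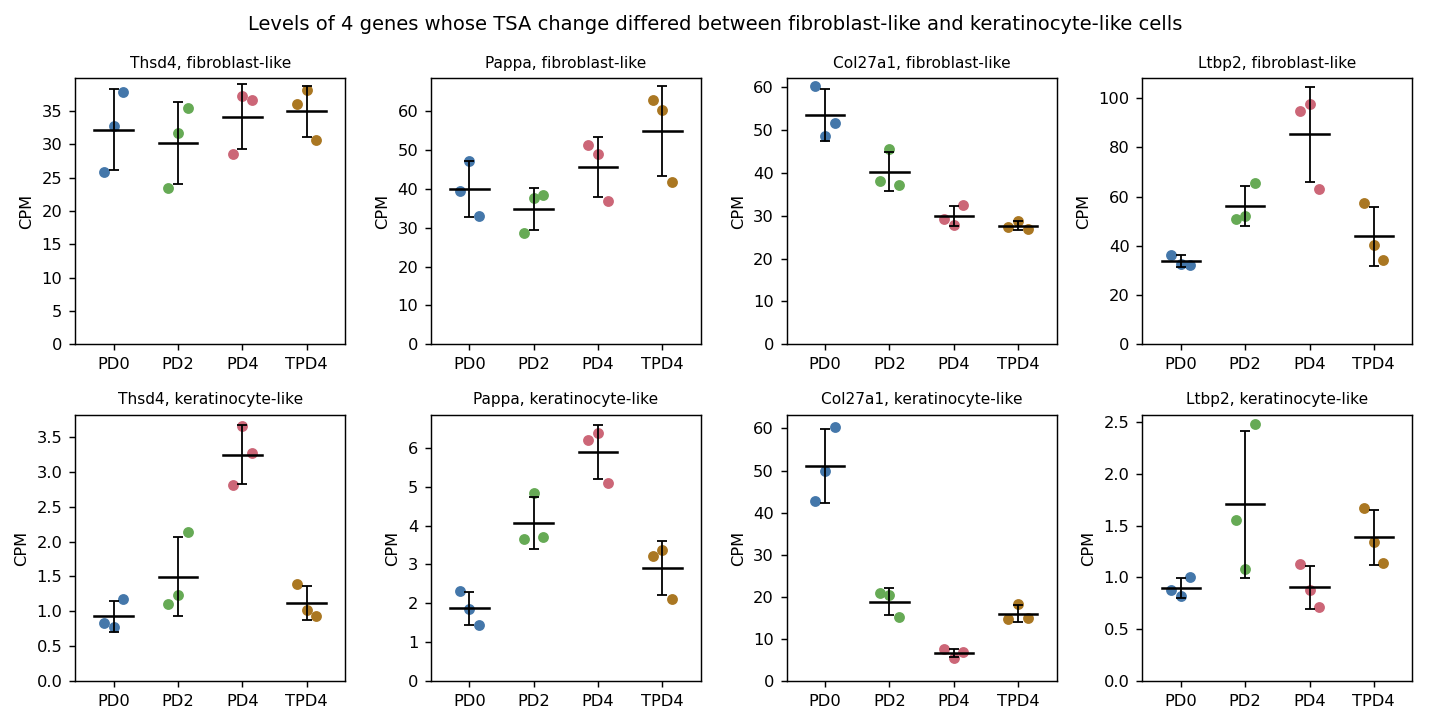
Levels (CPM of the summed counts of each library) of 4 of the 5 genes whose TSA change differed between fibroblast-like (upper panels) and keratinocyte-like cells (lower panels), by group. Points are libraries, lines are means and bars are SD (n = 3, drawn down to 0 at most); Col27a1 in keratinocyte-like cells averaged 6.65 CPM at PD4 and 16.0 CPM at TPD4.

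Endothelial-like cells, all in cluster 38, were few. Between PD0 and PD4 Oxct1, an enzyme of ketone body use, rose from 21.4 ± 11.1 to 89.2 ± 27.6 CPM (n = 3 libraries each; log2 change 2.26, SE 0.34, adjusted p = 0.0172) and Dynll1, a dynein light chain, from 493 ± 80.6 to 1043 ± 124 CPM. Fam13a fell from 33.2 ± 10.96 to 3.27 ± 2.95 CPM, Rhobtb1 from 48.8 ± 22.8 to 10.1 ± 0.0879, Clca3a1 from 79.4 ± 23.2 to 24.5 ± 14.04, Gprc5b from 71.3 ± 12.3 to 19.9 ± 9.35 and Galnt15 from 92.6 ± 25.7 to 21.3 ± 10.3 CPM. None of 15 imprinted growth genes passed over all genes, 7 fell adjusted over the list alone, and the list kept its camera call with an estimated correlation (adjusted p = 5.2e-06 and 0.0211) and with fry (0.00172). At the preset correlation camera called 7 lists in this comparison, and up to 13 when the same libraries were split otherwise. Plagl1, an imprinted zinc finger factor, stood at 152 ± 28.8 against 368.5 ± 93.8 CPM at PD0, Peg3 at 201.4 ± 29.1 against 770.2 ± 83.1, H19 at 457.5 ± 263 against 1228 ± 69.9 and Peg10 at 14.4 ± 16.0 against 68.1 ± 38.0. None of 35 cell cycle genes passed over all genes and 19 rose adjusted over the list alone (adjusted p = 0.575 with an estimated correlation), with Mcm6, Uhrf1, Ung and Tpx2 at 1.47, 2.49, 2.08 and 1.37. None of 28 genes of oxidative phosphorylation passed over all genes and 5 rose adjusted over the list alone (adjusted p = 0.575 with an estimated correlation), with Ndufb2, Atp5g1, Ndufa1 and Ndufa5 at 1.13, 0.90, 0.78 and 0.75. None of 12 endothelial markers passed over all genes and 4 fell adjusted over the list alone (adjusted p = 0.497 with an estimated correlation), with Ramp2, Egfl7, Pecam1 and Emcn at -0.86, -0.82, -0.53 and -0.67. None of 14 keratinocyte markers passed over all genes and 6 rose adjusted over the list alone (adjusted p = 0.575 with an estimated correlation), with Krt15, Krt79, Krt17 and Lgals7 at 2.13, 3.96, 1.83 and 2.14. In all, 12 of 7135 genes changed, 3 up and 9 down (1198 at an unadjusted p under 0.05; 86 by DESeq2), and 19.8% of tested genes did not overlap, against 10% by chance. The count was 2, 0 and 23 without PD0 replicates 1, 2 and 3, and 1, 80 and 0 without PD4 replicates 1, 2 and 3, of which PD4 replicate 2 held 11 such cells.

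With TSA no gene passed in endothelial-like cells by edgeR (250 of 7135 at an unadjusted p under 0.05; 0 by DESeq2). Of 35 cell cycle genes, 11 genes raised by histone deacetylase inhibitors in culture and 14 keratinocyte markers, none passed over all genes, and adjusted over the list alone 1 keratinocyte marker fell (adjusted p = 0.6004, 0.962 and 0.424 with an estimated correlation). For the inhibitor list, a median and mean of -0.02 and a downward rank in camera stood against an upward one in fry. Kif23, Mcm4, Cdk1 and Ube2c had changes of 0.57, 0.64, 0.58 and 0.57, Txnip, Cdkn1c, Sat1 and Clu of 0.52, -0.41, 0.46 and 0.54, and Perp, Krt15, Krt17 and Krt79 of -1.29, -1.66, -2.06 and -1.98. Grouping TPD4 replicates 1 and 2 with PD4 replicate 2 called 26 genes, and this grouping parts libraries by depth, with medians of 4877, 8435 and 8225 UMIs per endothelial-like cell against 2905, 3737 and 2483.

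Macrophage-like cells all lay in cluster 37. Retnla, a secreted protein of alternatively activated macrophages, had 0 counts among 1657051 UMIs at PD0 and 191 ± 183 CPM at PD4 (both here without the TMM factors), a mean at least 105-fold higher than the 1.81 CPM that 3 counts over the PD0 group would give. Without PD4 replicate 2, at 402 CPM, the mean was 85.7 CPM and at least 47-fold higher. Mgl2, a C-type lectin, rose from 58.4 ± 20.4 to 619 ± 101.1 CPM (n = 3 libraries each; log2 change 3.48, SE 0.35, adjusted p = 0.000166). Cd209f, another lectin, rose from 17.9 ± 4.12 to 182 ± 77.5, Ptpn7 from 3.62 ± 2.07 to 25.2 ± 6.70, and Ighm, the immunoglobulin mu chain of B cells, from 8.70 ± 8.59 to 180.3 ± 23.9 CPM. Adam8, a metalloprotease of leukocytes, fell from 79.0 ± 42.0 to 5.47 ± 1.98 CPM, Fkbp5 from 69.2 ± 42.8 to 5.33 ± 2.61, Igf2bp1, a fetal RNA-binding protein, from 27.7 ± 9.61 to 3.51 ± 2.49, Vcam1 from 49.8 ± 6.34 to 6.60 ± 5.29 and Hdc, histidine decarboxylase and a marker of mast cells, from 26.3 ± 17.4 to 4.34 ± 2.17 CPM. Hdc had log2 changes of -2.53 here, -2.48 in fibroblast-like and -2.60 in keratinocyte-like cells. Of 36 cell cycle genes 6 rose (20 adjusted over the list alone), with Uhrf1, Hells, Mki67 and Mcm6 at 1.88, 2.35, 1.44 and 1.21. Of 19 resident macrophage genes 6 rose and 1 fell (7 and 2 adjusted over the list alone), Igf1 from 274 ± 70.8 to 650.2 ± 77.6 CPM, Folr2, a folate receptor, with 1.29 and Selenop with 0.89. Of 6 complement genes 2 rose (2 adjusted over the list alone), among them C4b with 3.57, beside Cfb and Cd55 at 0.43 and -0.46. Of 13 imprinted growth genes Dlk1 alone fell (-4.25; 7 fell adjusted over the list alone), with Cdkn1c, Peg3 and Meg3 at -2.90, -1.92 and -2.80. Of 12 fibroblast markers Twist2 alone fell (-4.06; 5 fell adjusted over the list alone), with Dpt, Dcn and Col3a1 at -2.48, -2.22 and -2.21, and Dlk1 stood at 8.40 CPM at PD4 against 1288 CPM in fibroblast-like cells. Each of these 5 lists had an adjusted p of 0.389 with an estimated correlation.

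In all, 156 of 8426 genes changed between PD0 and PD4 in macrophage-like cells, 91 up and 65 down (180 by DESeq2), and 20.5% of tested genes did not overlap, against 10% by chance. The count was 43 and 62 without PD0 replicates 1 and 2, and 21 and 58 without PD4 replicates 2 and 3. With TSA no gene passed by edgeR (436 of 8426 at an unadjusted p under 0.05; 1 by DESeq2; 2 by edgeR without TPD4 replicate 1). None of 14 antigen presentation genes passed over all genes and 1 fell adjusted over the list alone (adjusted p = 0.444 with an estimated correlation), with H2-K1, Ccr2, Tap1 and H2-Eb1 at -0.53, -2.38, -0.97 and -2.09. None of 36 cell cycle genes, 10 genes raised by histone deacetylase inhibitors in culture and 12 fibroblast markers passed over all genes or adjusted over the list alone (adjusted p = 0.479, 0.950 and 0.479 with an estimated correlation). Uhrf1, Nusap1, Ccna2 and Birc5 had changes of -0.81, -0.61, -0.71 and -0.60, Cdkn1c, Klf2, H1f0 and Gadd45b of 1.51, -0.71, -0.42 and -0.39, and Fbn1, Twist2, Pdgfra and Dcn of 1.37, 2.25, 1.27 and 0.98.

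The share of cycling cells was compared to ask whether growth slows with age or with TSA. It was 12.8% ± 4.99 of fibroblast-like cells at PD0, 14.4% ± 3.26 at PD2, 10.7% ± 3.56 at PD4 and 10.6% ± 3.06 at TPD4 (n = 3), and 18.7% ± 3.75, 23.04% ± 3.596, 21.2% ± 1.14 and 22.0% ± 3.32 of keratinocyte-like cells. Among neutrophil-like cells, which do not divide, 0.971, 4.84, 10.3 and 2.86% of 103, 62, 58 and 35 cells pooled over libraries met the same rule, with median depths of 2705, 2946, 2272 and 3032.5 UMIs before thinning against 8486 to 11746 in fibroblast-like and 11527 to 14383 in keratinocyte-like cells. Fascia-like cells made up 1.92% ± 1.07 of fibroblast-like cells at PD0, 4.20% ± 1.74 at PD2, 6.71% ± 4.54 at PD4 and 4.36% ± 0.305 at TPD4 (for PD4 vs PD0, exact permutation p = 0.1 over all splits and 0.25 with same-numbered libraries as pairs, each the smallest possible). Without PD4 replicate 2, at 11.94%, the PD4 share differed by 2.17 percentage points from PD0 (4.79 with it) and by -0.114 from PD2 (2.50 with it). Some subclusters named papillary-like or reticular-like failed the marker check in at least 1 group, so their shares are not compared.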

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

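Among the tests in this part, the splits of libraries, all tests of dissociation stress, the tests within 1 class, the medians without PD0 replicate 1 and the comparison of all barcodes with kept cells were chosen after the results they weigh were seen.

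The TSA change of 5 genes differed between fibroblast-like and keratinocyte-like cells in a direct test. For 4 of them the log2 difference, fibroblast-like minus keratinocyte-like, was 1.6184 for Thsd4, 1.2968 for Pappa, -1.3724 for Col27a1 and -1.6165 for Ltbp2. In keratinocyte-like cells given TSA, Thsd4 and Pappa had log2 changes of -1.57 and -1.03 (adjusted p = 0.0265 and 0.0673). Ltbp2 (0.62) and all 12 fibroblast markers had positive changes there. Without genes below 1/10 of their level in another class, 18 differed. At TPD4 Thsd4, Pappa and Ltbp2 lay below that bound. They stood at 1.12, 2.91 and 1.39 CPM in keratinocyte-like and 34.9, 55.01 and 43.9 CPM in fibroblast-like cells.

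The levels of Zbtb16, Fkbp5, Per1 and Cirbp were higher at PD0, and 3 explanations were weighed. Dissociation stress could raise such genes, but the stress list, whose median change from PD0 to PD4 was -0.8576 in fibroblast-like cells, had a median of 0.4902 in keratinocyte-like cells, against this explanation for both classes. Another phase of the day could do so, and the positive clock arm lay 0.0236 above the negative arm in fibroblast-like and 0.7753 above it in keratinocyte-like cells, which leaves it undecided over both classes. A higher glucocorticoid signal at birth may be the biological cause, with medians of -0.5635 in fibroblast-like and 0.2376 in keratinocyte-like cells, also undecided over both. In macrophage-like and endothelial-like cells the glucocorticoid medians were -0.2451 and -0.5641, and the positive arm (3 and 2 genes) stood at -0.8636 and -0.5924 against -0.0978 and -0.7894 for the negative arm. Within fibroblast-like cells alone the values are consistent with stress (-0.8576) or glucocorticoids (-0.5635), which these data do not separate, and speak against another phase of the day (0.0236). Within keratinocyte-like cells alone they are consistent with another phase of the day (0.7753) and speak against stress (0.4902) and glucocorticoids (0.2376). PD0 replicate 1 stands apart, since 1535 of its 3690 fibroblast-like cells (41.6%) lay in subcluster 11, led by Ccl2, Cxcl2, Icam1, Irf1, Nfkbia, Btg2, Csrnp1 and Atf3, a subcluster of 1741 cells in all. Without it the fibroblast-like medians from PD0 to PD4 were -0.4148 for stress and -0.2292 for glucocorticoids, the second no longer below the bound of -0.3 set for it.

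The TSA change of fibroblast-like cells ran opposite to the change from PD0 to PD2. RNA from other cells could produce this, but r was -0.2697 over the 4445 genes highest in fibroblast-like sums among the 4 tested classes. Classes not tested were left out of that ranking, so RNA from them was not addressed. Wif1 and Stmn2 were highest in clusters 13 and 25 of such classes. Another mix of fibroblast subclusters could also do so. Over the pooled cells of 3 subclusters r was -0.2669, against -0.2534 to -0.1592 in 20 draws of as many random cells. Pooling did not hold the mix among the 3 fixed, and none of them was named papillary-like. Cluster 10, where Fap, Ssc5d, Wfdc1 and Lypd2 were highest, held 17.9% of pooled fibroblast-like cells at PD4 and 12.8% at TPD4. Cluster 2 (Penk) held 0.422 and 1.79%, and cluster 5 (Sncb, Prss50) 27.5 and 27.8%. A changed mix is therefore left undecided. A partial return towards a younger state under TSA may also play a part, but the stress list had medians of -0.4357 from PD0 to PD2 and 0.301 with TSA. Without PD0 replicate 1 the first median was 0.0042 and r over all tested genes was -0.201, against -0.214 with it. Without a vehicle group, injection and TSA cannot be told apart.

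Fibroblast-like cells of 3 subclusters (2676 cells) were nearly missing from the replicate 1 libraries. Their mean share of fibroblast-like cells was 0.187% there, against 5.01 to 11.7% in the other 8. The 3 were picked, after the shares were seen, for holding few cells in every replicate 1 library and more in the others. The exact permutation p of 0.00202, the smallest possible over 495 regroupings, follows from that choice and is no independent test. Loss in the cell filter was first tested by the regional and cartilage genes over all barcodes, 14.2 CPM in replicate 1 and 52.4 elsewhere, a ratio of 0.2702, which lies between the bounds set before. Within replicate 1, all barcodes held 1.0115 times the level of kept cells, which speaks against loss in the filter. Tissue of the head or neck in the other libraries is a candidate explanation, since 39 Hox genes, low in head mesenchyme, held 73.2 CPM in these subclusters and 504 CPM in other fibroblast-like cells, a ratio of 0.1452. No biological explanation tied to age or TSA was tested, as replicate 1 spans all 4 groups.

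Splits of the 6 libraries of a comparison are too few (10) to give a p under 0.1. Only 1 of 10, the real one, called as many genes in fibroblast-like cells for PD2 vs PD0 (1901, highest other 0), PD4 vs PD2 (8, 0), PD4 vs PD0 (3433, 0) and TPD4 vs PD4 (17, 0), in keratinocyte-like cells for PD4 vs PD0 (3784, 0) and TPD4 vs PD4 (72, 0), in endothelial-like and macrophage-like cells for PD4 vs PD0 (12 with 3, and 156 with 0), and for the difference of the TSA change (5, 0). In the fibroblast-like comparisons read as paired, the 3 other splits that part all 3 pairs also called 0 genes. For TPD4 vs PD4 all 10 called as many in endothelial-like (0, highest other 26) and macrophage-like cells (0, 0). Camera list calls at the preset correlation mostly did not single out the real split. Numbers of lists called by the real split and the highest other follow in the order above. They were 7 and 22, 25 and 23, 17 and 19, and 25 and 18 in fibroblast-like cells. For PD4 vs PD0 and TPD4 vs PD4 these were 14 and 24, and 12 and 20, in keratinocyte-like cells. They were 7 and 13, and 13 and 14, in endothelial-like cells, and 14 and 18, and 14 and 21, in macrophage-like cells. The r of TSA against age was largest in size in 1 of 10 (-0.214, highest other 0.159).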

How the results depend on the processing

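Of 421 named gene results under 8363 alternatives, 7511 kept their direction and side of the threshold, 541 became weaker, 261 stronger, 48 moved and 2 turned. Of 850 alternatives of 85 list results, 666 stayed, 148 weakened, 16 strengthened and 20 moved. Fry lost 43 preset camera calls. For TSA, r with PD2 vs PD0 and the covariance with PD4 vs PD0 kept their sign in all 36. Without any effect the covariance is negative too (-0.0717 simulated). Of 213 alternatives of the gene counts 112 stayed within 1.5 times, and of 780 share values 744 stayed. With 3 libraries per group, the endothelial-like and macrophage-like counts also rest on few cells. The cause was not tested where none is given.

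In the lists below F, K, E and M stand for genes changed in fibroblast-like, keratinocyte-like, endothelial-like and macrophage-like cells. A mean of at least 20 CPM, which tests fewer genes, gave F 961 (PD2 vs PD0), 0 (PD4 vs PD2), 1545 (PD4 vs PD0) and 4 (TPD4 vs PD4), K 1296 (PD4 vs PD0) and 19 (TPD4 vs PD4), and 2 for the difference of the TSA change. A minimum fold of 1.5 gave F 122, 0, 692 and 6, K 857 and 8, E 0 and M 20 (both PD4 vs PD0) in the same order. No filter on low counts gave F 75 (PD4 vs PD2) and 48 (TPD4 vs PD4), K 187 (TPD4 vs PD4), E 481 and M 613 (PD4 vs PD0), and E 80 and M 137 (TPD4 vs PD4). Thinned sums gave F 1250 (PD2 vs PD0) and 2 (PD4 vs PD2), K 44 (TPD4 vs PD4), E 1 and M 56 (PD4 vs PD0), and M 1 (TPD4 vs PD4). Fits of only 6 libraries gave F 0 (PD4 vs PD2) and 1894 (PD4 vs PD0), K 2257 (PD4 vs PD0) and 21 (TPD4 vs PD4), and M 69 (PD4 vs PD0). DESeq2 gave F 248 (PD4 vs PD2) and 155 (TPD4 vs PD4), K 315 and M 1 (TPD4 vs PD4), E 86 (PD4 vs PD0), and 168 for the difference. Stricter cells gave E 53 and M 85 (PD4 vs PD0), and no doublet removal F 4 (PD4 vs PD2). Without genes below 1/10 of another class, F was 2 (PD4 vs PD2), E 74 (PD4 vs PD0), M 1 (TPD4 vs PD4) and the difference 18. Chosen after seeing the data, leaving out the regional subclusters gave F 21 (PD4 vs PD2), and leaving out PD2 replicate 3 and PD4 replicate 2 gave F 769 (PD2 vs PD0), 0 (PD4 vs PD2), 1726 (PD4 vs PD0) and 7 (TPD4 vs PD4), K 12 (TPD4 vs PD4), E 75 and M 16 (PD4 vs PD0).

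Leaving out cycling cells gave F 4 (PD4 vs PD2), K 43 (TPD4 vs PD4), E 0 and M 34 (PD4 vs PD0), and M 2 (TPD4 vs PD4). It turned Mki67 to 0.97 (adjusted p = 0.0327 by edgeR) from -0.11 and Cenpa to 0.0934 from -0.80 for PD4 vs PD0 in fibroblast-like cells, 2 of the 8 genes by which cells were left out. Without each library in turn, F ranged over 825 to 1925 (PD2 vs PD0), 0 to 17 (PD4 vs PD2), 2205 to 3343 (PD4 vs PD0) and 6 to 14 (TPD4 vs PD4), K over 2371 to 3859 and 10 to 69, E over 0 to 80 (PD4 vs PD0), M over 21 to 166 (PD4 vs PD0) and 0 to 2 (TPD4 vs PD4), and the difference over 0 to 10.

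With the replicate number as a block, F was 3453 (PD2 vs PD0) and 69 (TPD4 vs PD4), where every pair correlation was over 0.1. In TPD4 vs PD4 all 6 libraries correlated best with their own number, but in PD2 vs PD0 only 2 did. The pairing is therefore weakly borne out for PD2 vs PD0. Where a pair fell short, F was 133 (PD4 vs PD2), K 235 (TPD4 vs PD4) and E 113 (PD4 vs PD0). Among these, every library correlated best with its own number only in E. The lowest pair correlations there were -0.0432, 0.0949 and 0.0636. The block moved no other count by over 1.5 times.

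As a share of named non-keratinocyte cells, differences in percentage points were 1.782 (0.7105 among all cells) for E in PD4 vs PD2, for M 1.348 (0.1934) in PD4 vs PD2, 1.759 (0.4516) in PD4 vs PD0 and -1.206 (-0.1905) in TPD4 vs PD4, and for T or innate lymphoid-like cells 1.759 (0.9687) in PD2 vs PD0, 10.37 (2.806) in PD4 vs PD2, 12.13 (3.775) in PD4 vs PD0 and -10.36 (-2.968) in TPD4 vs PD4. For dendritic or Langerhans-like cells they were 7.146 in PD4 vs PD0 and -5.856 in TPD4 vs PD4. Without thinning, the differences of cycling shares were 5.978 (1.592) and 2.81 (-2.107) in F for PD2 and PD4 against PD0, and 8.03 (4.287) and 8.519 (2.423) in K. Median depth was higher at PD2 but not at PD4.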

Other observations

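No test was run in this part, and its values were chosen after they were seen.

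Dermal sheath or myofibroblast-like cells made up 1.502% ± 0.335 of cells at PD0 and 3.42% ± 1.31 at PD2 (n = 3 libraries each), with 4.01, 4.32 and 1.92% in PD2 replicates 1, 2 and 3, and 2.46% ± 1.21 at PD4 and 3.82% ± 1.399 at TPD4. Dermal papilla or condensate-like cells made up 1.498, 1.19 and 1.26% at PD0, 4.84, 3.17 and 1.497% at PD2, 5.64, 0.823 and 4.85% at PD4, and 5.48, 3.37 and 3.07% at TPD4. Dkk1 and Ntsr1, both lower in fibroblast-like cells at PD4 than at PD2, were highest in the dermal sheath or myofibroblast-like clusters 25 (144 CPM) and 30 (8.36 CPM). Wif1 was highest in the dermal papilla or condensate-like cluster 13 (1518 CPM).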
